A study of Mus musculus with 2 samples.

How the data were processed

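The series measured H3K4me1, histone H3 carrying 1 methyl group on lysine 4, by chromatin immunoprecipitation and sequencing (ChIP-seq). In this assay chromatin is fragmented, fragments bound by an antibody are recovered and sequenced, and stretches of the genome with more fragments than a background are reported as peaks. H3K4me1 is known as a mark of enhancers and of the flanks of promoters. The tissue was mouse forebrain at embryonic day 11.5 from strain B6NCrl. There was 1 group of 2 biological replicates, and each was a pool of male and female embryos. Replicate 1 held the forebrains of 109 embryos and replicate 2 those of 88, per the labels. Each replicate joined technical replicates 1 and 2, and a fragment size range of 300 to 500 was given without its unit. With 1 group there was no contrast between conditions, so the replicates were compared with each other and the peaks with chance placements.

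The deposited files are 4 peak lists on the mouse genome build mm10: 1 for each replicate, 1 for both replicates pooled, and 1 of replicated peaks derived from the pooled list and both replicate lists, per the readme text deposited with the samples. The peak caller, the aligner, their versions and thresholds, and the rule for a replicated peak are not given in the sources used here. A control experiment is named in the labels and was not analysed here, and read totals were not given in the sources used here. For each peak the deposited lists give a fold, the ratio of fragment pileup to expected background, and the −log10 of a p-value and of a q-value.

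What the authors' columns hold was tested on the values themselves. In peaks where the background was constant, the deposited fold times the background plus 1, minus 1, was a whole number of fragments, and the deposited −log10 p-value was the Poisson upper tail of that number. The peaks that met this within 0.02 of the scaled fragment number and 0.01 of the −log10 p made up 45.9% of replicate 1, 44.1% of replicate 2 and 43.4% of the pooled list. The implied background was 1.86 fragments in replicate 1, 2.05 in replicate 2 and 2.12 in the pooled list, and 1 fragment of the pooled list counted as 0.541 in its fold. Among the peaks that met these limits, the median pileup at a peak's top was 9 fragments in replicate 1 and 10 in replicate 2. The fold of 1 such peak thus rests on few fragments. A fold per peak is the authors' own value, set against each list's own background. It was used to describe, rank or filter peaks within a list, to correlate overlapping peaks of the replicates, and to count the peaks of each replicate above the same fold. All 4 lists reached down to a −log10 p near 2, which is a permissive threshold, and the share of peaks with a −log10 q of at least 2 was 42.0% in replicate 1, 60.6% in replicate 2, 32.2% in the pooled list and 39.3% in the replicated list.

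The genome was GRCm38.p6, the assembly behind mm10, and genes came from GENCODE vM21 on chromosomes 1 to 19 and X. A gene's transcription start site (TSS) was the 5′ end of its longest protein-coding transcript, which gave 21670 protein-coding genes. The replicated list was the main list, and both replicate lists served as its error. Overlap meant at least 1 bp. Chance levels came from circular shifts, in which all peaks of a chromosome are moved by 1 random distance: 1000 for the replicate overlap and for the TSS distances of the replicated list, and 100 for annotation classes and for the TSS distances of the other lists. Peak centres were sorted into distances of up to 1 kb, 1 to 5 kb, 5 to 50 kb and over 50 kb from a protein-coding TSS. Peak bases were assigned to coding exon, untranslated region (UTR), non-coding exon, intron or intergenic sequence, in that order. The TSS profile gave the share of TSSs with a peak at each 100 bp step to 5 kb. Shares of peaks have 95% Wilson binomial intervals. All intervals cover counting error only.

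For each gene the percent of the 100 kb window centred on its TSS that lay in peaks was computed. A window can hold peaks of neighbouring genes. Before the data were examined, 22 lists were fixed: telencephalon and forebrain patterning, ventral telencephalon and interneuron lineage, dorsal telencephalon neuron lineage, diencephalon with hypothalamus and eye field, neural progenitor, pan-neuronal, mature neuron subtype and synapse, astrocyte and oligodendrocyte, midbrain and hindbrain, Hox clusters, secreted patterning signals, head mesenchyme and meninges, endothelium, erythroid and early blood, macrophage and microglia, surface epithelium, liver, heart, skeletal muscle, gut with pancreas and lung endoderm, housekeeping, and the olfactory receptor family. A list's median was placed among 10000 random lists of the same size matched on decile of gene length. A list stood apart when its median lay within the highest or the lowest 2.5% of random lists, which chance gives for 1.1 of 22 lists. Genes are not replicates, so the median of a list was given no p-value. A later comparison of transcription factor genes with the other members of 9 lists did permute genes; it treats them as independent, although some share a window. Each member was also ranked within the genes of its own length decile, where 10% lie above the 90th percentile by chance.

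Genes were named by a rule fixed at the same time. It took the 3 members of each forebrain, brain, signal or general list with the largest covered percent and the 1 with the smallest, and 2 and 1 for lists of other tissues or cell types. It also took the 20 protein-coding genes with the largest covered percent at TSSs 100 kb apart, the 10 clusters with the most bases in peaks, the 5 genes in each direction with the largest difference between replicates at equal list length, and the 5 peaks with the largest fold. Where other genes are named, they were chosen after their values were seen, and the text says so. Clusters joined replicated peaks less than 5 kb apart.

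Motif density was counted on both strands in replicated peaks centred over 5 kb from a TSS. It was compared with flanks of equal width 3 kb outside each border that met no pooled peak, and each density was divided by the mean density of all other orderings of the motif's bases with the same number of CpG dinucleotides. Ratios are means and SDs over 19 autosomes. A promoter was called CpG-rich when the 1 kb around its TSS had an observed over expected CpG of at least 0.6 and a GC fraction of at least 0.5. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

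The steps were tested on simulated data. Of 67641 simulated peaks, 50.0% were planted as shared and 50.6% were recovered, with 2.14% by chance. Gene lists with nothing planted among 21670 genes fell within the highest or lowest 2.5% in 2% of trials, and lists with 2 percentage points of coverage planted were found in 100%. These simulated lists held 15 genes drawn without regard to position. They do not give the rate for lists whose members share windows, such as the Hox clusters. A motif planted at a ratio of 2 was recovered at 1.89, and at 1.00 with nothing planted. A planted X dose of 0.6 was recovered between 0.583 and 0.600 when the pileups themselves were known.

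Alternatives fixed before the data were examined were overlaps of 50% of a peak or of both peaks, equal list lengths, a −log10 q of at least 2, the stronger part of each list split at its median fold, the pooled list, each replicate's list alone, TSSs of all gene types, the nearest edge of a peak, windows of 50 and 200 kb, gene bodies with 10 kb on each side, peak numbers, matching on gene density within 500 kb, clustered genes counted once, a shorter joining distance of 1 kb and a longer one, flanks 10 kb away and flanks matched on GC in steps of 5 percentage points. Matching random lists on window GC, matching them on promoter CpG class, and the 5′ ends of all transcripts were added after seeing the data. The summary value followed for the TSS profile, the share at the TSS over the downstream maximum, was also chosen after seeing the data. The 4 replicate 1 peaks outside chromosomes 1 to 19 and X were left out because the chromosomes used for chance levels and genes do not include them.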

Results

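H3K4me1 was profiled in 1 group, mouse forebrain at embryonic day 11.5, in 2 biological replicates that were each a pool of embryos of both sexes. The list of replicate 1 held 90618 peaks, that of replicate 2 held 163518, the pooled list held 85078 and the list of replicated peaks held 67641. The replicated list covered 25.3 Mb, or 0.990% of the known sequence of build mm10, against 23.4 Mb in replicate 1 and 54.1 Mb in replicate 2. Peaks were short, with a median width of 289 bp in the replicated list, 207 bp in replicate 1 and 239 bp in replicate 2. The median fold of pileup over background, the authors' own value, was 3.55 in the replicated list and 3.49 in each replicate. Sequencing depth in reads is unknown; the background implied by the values was 1.86 fragments in replicate 1 and 2.05 in replicate 2, a ratio of 1.10.

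The first question was where the mark was most extensive. The gene with the largest share of its 100 kb window in replicated peaks was Gse1, which encodes a coiled-coil protein found in histone deacetylase complexes, at 50.2% (41.8% in replicate 1 and 58.7% in replicate 2). Among genes with TSSs 100 kb apart, next came Ncor2, a corepressor of nuclear receptors, at 30.7%, Tle3, a corepressor of the Groucho family, at 28.1%, Bahcc1 at 27.3%, the cell adhesion gene Flrt1 at 27.2% and the zinc finger gene Cxxc5 at 26.4%. The retinoic acid receptor gene Rara had 25.8% and Crabp2, which encodes a retinoic acid binding protein, 21.2%. Notch1, the receptor that keeps neural progenitors undifferentiated, had 23.7%, the Polycomb gene Cbx8 22.9%, Prdm16, a regulator of neural progenitors, 21.8%, and the ephrin ligand gene Efna2 21.7%. The median over all 21670 protein-coding genes was 0.831%, and 28.4% of them had no replicated peak in their window.

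The remaining genes among the 20 with the largest covered share at TSSs 100 kb apart, which leaves out neighbours that share a window, were G430095P16Rik (25.6%), Ccdc85c (24.6%), Ifrd2 (24.1%), Gins2 (22.0%), Pipox (22.0%), Fam222a (21.9%), Igdcc3 (21.9%) and Tcf20 (21.5%). Gins2 is the gene next to Gse1: its TSS lies at position 120589304 of chromosome 8 and that of Gse1 at 120488447. The Gins2 window reaches into Gse1, which ends at 120581390, and most of the peak bases in that window lie inside Gse1. The lowest share among the 20 was 16.9% in replicate 1, at Efna2, and 26.4% in replicate 2, at Crabp2.

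Replicated peaks less than 5 kb apart formed 30040 clusters, of which 15348 were single peaks. The 538 clusters with at least 10 peaks held 15.3% of all bases in peaks. The largest lay in Gse1, at chromosome 8 from 120484390 to 120566188, with 63 peaks covering 56.1 kb (47.2 kb in replicate 1 and 63.8 kb in replicate 2), and it contained the TSS of the longest Gse1 transcript. A further cluster inside the Gse1 gene, from 120260897 to 120310618, was the last of the 10 broadest with 22.3 kb covered. Msi2, which encodes an RNA-binding protein of progenitor cells, held the clusters ranked second and ninth, both inside the gene on chromosome 11, at 88478960 to 88568353 (32.5 kb covered) and at 88574309 to 88632452 (22.3 kb). The cluster on chromosome 7 from 79508149 to 79558704 (30.5 kb) met no protein-coding gene; the nearest protein-coding TSS was that of Polg, and the annotation places the long non-coding RNA genes Mir9-3hg and Gm35040 there. The cluster on chromosome 3 from 88192520 to 88243631 (24.6 kb) overlapped Rhbg and Gm38392 and contained the microRNA gene Mir9-1. The others were at Tle3 (chromosome 9, 61360171 to 61406675, 25.3 kb), Ssbp3, a cofactor gene of LIM homeodomain factors (chromosome 4, 106933933 to 107003139, 24.8 kb), Rara (chromosome 11, 98924681 to 98971784, 23.5 kb) and Prdm16 (chromosome 4, 154567747 to 154604700, 22.6 kb). Which clusters ranked in the first 10 depended on the setting: 5 of the 10 remained with a joining distance of 1 kb, 5 with the longest distance tried, 5 with peaks at a −log10 q of at least 2, and 6 in the list of replicate 2 alone.

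**Figure D1:**
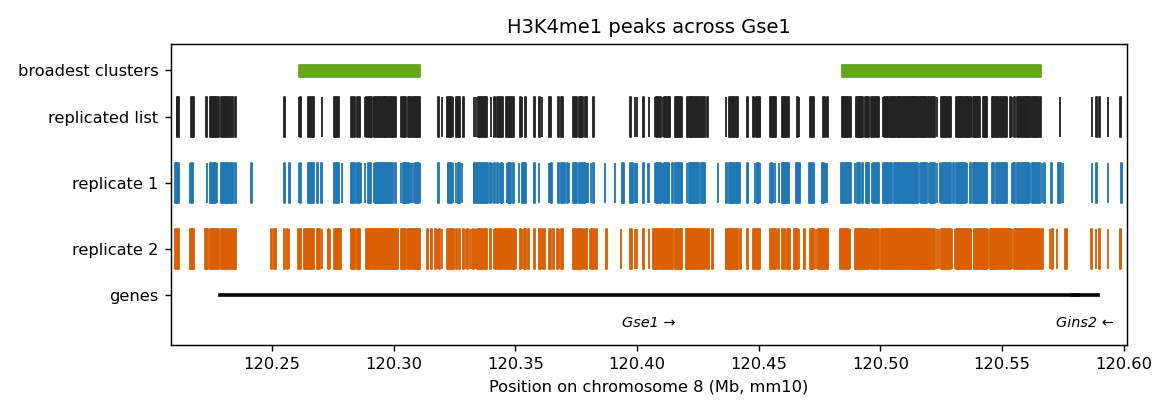
Peaks across Gse1 on chromosome 8 of mm10 (position in Mb), drawn as bars for the replicated list (197 peaks in the region), replicate 1 (298) and replicate 2 (264), with the 2 clusters in the gene that rank among the 10 broadest and the genes Gse1 and Gins2 with their strands. The denser cluster, at the right, surrounds the TSS of the longest Gse1 transcript at 120488447 and extends downstream of it.

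The peaks with the largest fold lay at Ephb2, Tle2, Notch1 and Zfp423. The first of 5 was in an intron of Ephb2, an Eph receptor gene, at chromosome 4 from 136756537 to 136758848, with a fold of 9.81 (7.98 in replicate 1 and 11.1 in replicate 2). The second, at chromosome 10 from 81569013 to 81569402, was intergenic, 6324 bp from the TSS of the corepressor gene Tle2, with a fold of 8.90. A pair lay in introns of Notch1 on chromosome 2, from 26487694 to 26490578 (fold 8.84) and from 26485855 to 26487413 (8.82), and the last in an intron of the zinc finger gene Zfp423 on chromosome 8 from 87937256 to 87939742 (8.82).

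Whether the mark followed the regional and cell identity of the tissue was asked with 22 gene lists fixed before the data were examined. Genes of neural progenitors had the largest median coverage, 6.78% of the window against 0.760% for random lists of genes of like length (replicate 1 6.19%, replicate 2 12.6%; 20 genes). Genes of telencephalon and forebrain patterning followed with 6.30% against 0.998% (18 genes), then ventral telencephalon and interneuron lineage with 5.26% against 0.857% (14 genes), diencephalon, hypothalamus and eye field with 4.90% against 0.880% (17 genes) and dorsal telencephalon neuron lineage with 3.93% against 0.717% (14 genes). Genes of midbrain and hindbrain had 4.20% against 0.705% (15 genes) and secreted patterning signals 3.24% against 0.838% (16 genes). Medians of liver (0.356% against 0.892%), erythroid and early blood (0.265% against 0.964%) and macrophage and microglia genes (0.736% against 0.795%) were below those of random lists, within the range chance gives. Of 22 lists, 9 lay within the highest 2.5% of random lists in the replicated list and in both replicates. Another 1 lay within the lowest 2.5%, and chance gives 1.1 lists over both ends together.

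In the forebrain patterning list, 9 of 18 genes lay above the 90th percentile of genes of their length, where chance gives 1.8. The largest shares were those of Pax6 (11.9%; TSS at chromosome 2, 105671860), Fezf2 (11.9%; chromosome 14, 12345844) and Lhx2 (8.25%; chromosome 2, 38350759), transcription factor genes that pattern the cortex and the eye. The smallest was that of Arx, at 0.506%, which lies on chromosome X. The list's percentile was 100, and between 99.98 and 100 over the 11 alternatives. In the ventral list, 5 of 14 genes were above the 90th percentile (1.4 by chance; percentile 99.98), led by the basic helix-loop-helix genes Olig2 (13.4%; chromosome 16, 91225457) and Olig1 (12.2%) and the homeobox gene Dlx1 (8.82%). Nkx2-1, which specifies the ventral telencephalon and hypothalamus, had 0.607%. In the dorsal list, 7 of 14 were above it (percentile 99.87), with the largest shares at Bcl11b, a zinc finger gene of cortical projection neurons (20.1%; chromosome 12, 108003602), and the helix-loop-helix genes Neurog1 (13.4%) and Nhlh1 (12.7%). Reln, which encodes the extracellular protein reelin, had 0.541%. In the diencephalon list, 4 of 17 were above it (percentile 99.99), and Tcf7l2 (9.93%), Gbx2 (7.97%) and Dbx1 (7.52%) had the largest shares and Vax2 (1.11%) the smallest.

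Of the neural progenitor genes, 11 of 20 lay above the 90th percentile for their length (2 by chance; percentile 100). Notch1 (23.7%; chromosome 2, 26503822), Nes, which encodes the intermediate filament nestin (19.03%; chromosome 3, 87971093), and the SoxB1 factor gene Sox1 (15.8%; chromosome 8, 12395295) led the list, and Prom1 had 0.319%. The window of Nes largely overlaps that of Crabp2 (TSS at chromosome 3, 87948666), so the shares of these genes do not stand for separate loci. Lists of differentiated cells did not stand apart. The pan-neuronal genes had a median of 1.12% against 0.666% (percentile 85.6), with Rbfox3 (6.26%), Elavl3 (5.74%) and Ncam1 (4.43%) at the top and Celf4 at 0. The genes of mature neuron subtypes and synapses had 1.65% against 0.808% (percentile 90.8), led by Camk2a (11.9%), Slc32a1 (5.95%) and Slc17a7 (5.82%), and Vip was listed at 0. Astrocyte and oligodendrocyte genes had 1.49% against 1.03% (percentile 72.2), led by Sox10 (6.29%), Cnp (3.75%) and Gfap (2.86%), with Plp1, on chromosome X, at 0.

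The lists of midbrain and hindbrain, secreted patterning signals and Hox clusters stood apart as well. In the midbrain and hindbrain list 5 of 15 genes lay above the 90th percentile (percentile 99.98): Pax7 (13.1%; chromosome 4, 139833528), Lmx1b (10.8%) and Pax2 (8.41%), transcription factor genes of the dorsal neural tube and the midbrain-hindbrain boundary, had the largest shares, and Pax8 (1.12%) the smallest. Among the secreted signals, 6 of 16 were above it (percentile 99.79), led by Wnt7b (8.49%), Bmp7 (7.78%) and Fgf15 (7.37%), with Rspo3 at 0.168%. The 39 Hox genes, which pattern the body axis behind the forebrain, had a median of 2.57% against 0.774% (percentile 99.77), but 2 of 39 lay above the 90th percentile, fewer than the 3.9 that chance gives. Hoxd8 (6.67%), Hoxd4 (6.14%) and Hoxd3 (5.68%) had the largest shares, and Hoxc13 was listed at 0. The percentile of the Hox list was 79.4 when members within 100 kb of each other counted once, and 9.07 when random lists were also matched on the GC content of the window, an alternative added after seeing the data. Matched on promoter CpG class, also added after seeing the data, it was 94.3. Under these added alternatives the lists of neural progenitors, the 4 forebrain lists, midbrain and hindbrain, and secreted signals had percentiles of 99.5 or above (window GC) and 99.35 or above (promoter CpG class).

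Head mesenchyme and meninges genes had 2.08% against 0.775% (percentile 98.5), led by Prrx2 (6.47%) and Pdgfrb (4.35%), with Col3a1, a collagen gene, at 0; the percentile was 96.6 with 200 kb windows and 97.0 when matched on promoter CpG class. The other lists lay within the range of random lists: endothelium (1.48%; percentile 90.6; Egfl7 4.12%, Esam 3.99%, Emcn 0), erythroid and early blood (percentile 9.99; Klf1 7.64%, Nfe2 7.37%, Spta1 0), macrophage and microglia (45.7; C1qb 8.82%, C1qc 5.88%, Mrc1 0), surface epithelium (1.66%; 88.0; Grhl3 6.75%, Tfap2c 6.49%, Perp 0), liver (13.1; Apoa2 6.07%, Foxa3 3.19%, Cps1 0), heart (2.00%; 94.4; Tnni3 5.19%, Myh7 4.37%, Actc1 0.590%), skeletal muscle (1.58%; 77.1; Tnnt3 8.48%, Des 6.89%, Myf5 0.231%), gut, pancreas and lung endoderm (2.05%; 88.2; Cdx1 5.49%, Sftpc 2.67%, Cdx2 0.458%) and housekeeping (2.15%; 92.6; Polr2a 7.27%, Rpl13a 5.47%, Hmbs 5.42%, and Hprt, on chromosome X, at 0). Some windows were shared, as between Cdx1 (TSS at chromosome 18, 61036199) and Pdgfrb (61045200). The housekeeping list reached the highest 2.5% under 5 alternatives, among them the list of replicate 2 (99.59), and the endoderm list did with 50 kb windows (97.62). Under the added matching the heart list reached 98.4 on promoter CpG class, and the macrophage list 0.25 on window GC.

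Of 1133 olfactory receptor genes, which are expressed in the nose, 1050 had no replicated peak in their window, and their median of 0 lay below all random lists in the replicated list and in both replicates. The largest shares were at Olfr221 (8.97%), Olfr1513 (4.31%) and Olfr90 (2.90%), and Olfr1413 was at 0. Random lists matched on window GC also had a median of 0 (percentile 50), so among genes of like window GC the family did not stand apart. Matched on promoter CpG class, the typical random list was at 0 too, but some lay above it (percentile 25.9). Because 0 is the floor, the added matching cannot show whether the family lies below such genes.

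**Figure D2:**
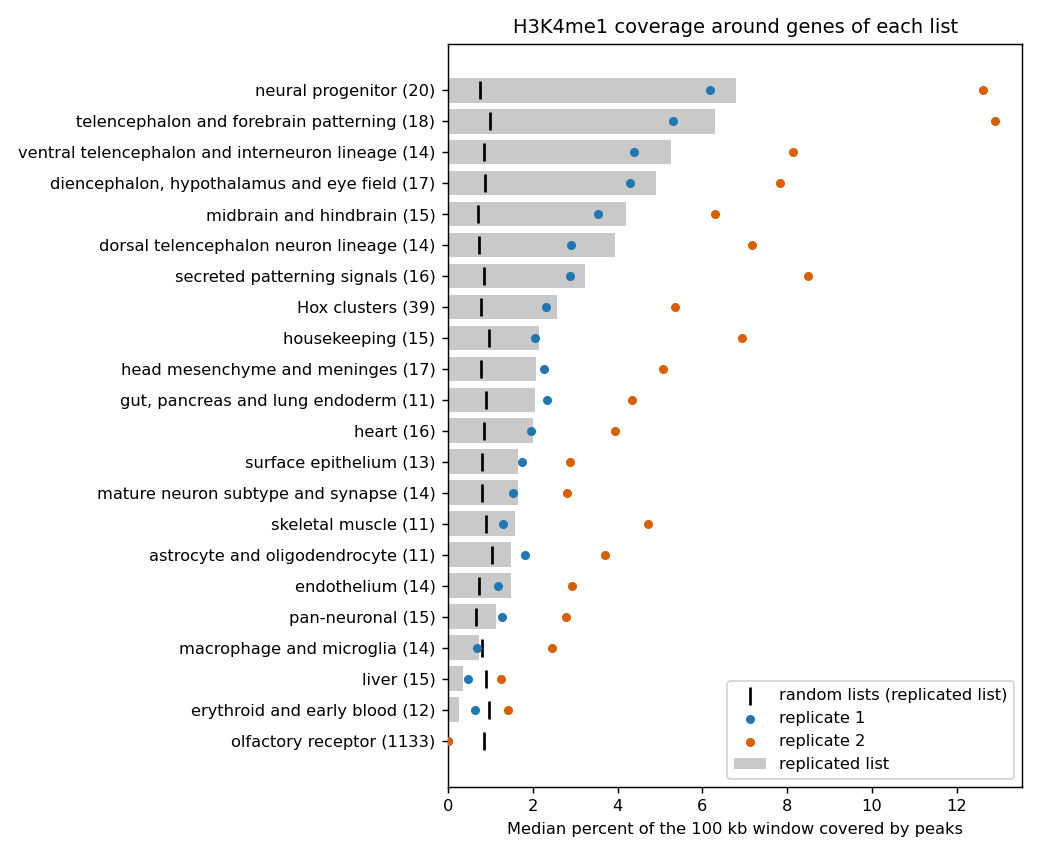
Median percent of the 100 kb window covered by peaks for the genes of each of 22 lists, with the number of genes in brackets: bars for the replicated list, points for replicates 1 and 2, and ticks for the median of random lists set against the replicated list. The 7 lists of neural progenitors, forebrain regions, midbrain and hindbrain, and secreted signals have the longest bars, between 3.24% and 6.78%, and olfactory receptor genes are at 0.

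Where peaks lay relative to genes was asked next. Replicated peaks were enriched near promoters and inside genes, yet most were distal: 67.9% were centred over 5 kb from a protein-coding TSS (72.0% in replicate 1 and 73.4% in replicate 2), against 91.8% by chance. Within 1 kb lay 13.3% (95% interval 13.1 to 13.6) against 1.72% by chance, between 1 and 5 kb 18.7% against 6.45%, between 5 and 50 kb 32.5% against 35.4%, and beyond 50 kb 35.4% against 56.4%. Introns held 59.6% of peak bases (43.7% by chance), intergenic sequence 27.4% (51.1%), coding exons 4.22% (1.54%), UTRs 3.74% (1.67%) and non-coding exons 4.99% (1.99%), and the shares in both replicates were on the same side of chance for each annotation class. These shares of the replicated list lay outside the range of the shifts, but between 5 and 50 kb narrowly (lowest shift 32.5498%, replicated list 32.5143%), and there both replicates lay within their own ranges (35.6% in replicate 1, shifts 33.4% to 37.5%; 33.6189% in replicate 2, shifts 33.5865% to 36.9189%).

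At the TSS itself the mark dipped. In the replicated list 4.64% of TSSs lay in a peak, against 7.41% of positions 500 bp upstream and 13.9% of positions 900 bp downstream. The dip was in both replicates, with 4.12% at the TSS and 10.5% downstream in replicate 1, and 9.16% and 23.3% in replicate 2. It was deep at CpG-rich promoters, where 3.86% of TSSs lay in a peak against 12.4% at the upstream and 23.7% at the downstream maximum. It was shallow at other promoters, with 5.30% at the TSS, 5.53% upstream and 6.26% downstream (10.6%, 10.9% and 11.6% in replicate 2). In replicate 1 these promoters had no dip against the upstream side, with 4.55% at the TSS, 4.49% upstream and 5.27% downstream. A peak lay within 1 kb of 56.5% of the 10016 CpG-rich promoters (52.8% in replicate 1 and 82.5% in replicate 2) and of 21.2% of the 11654 others (22.4% and 34.0%).

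**Figure D3:**
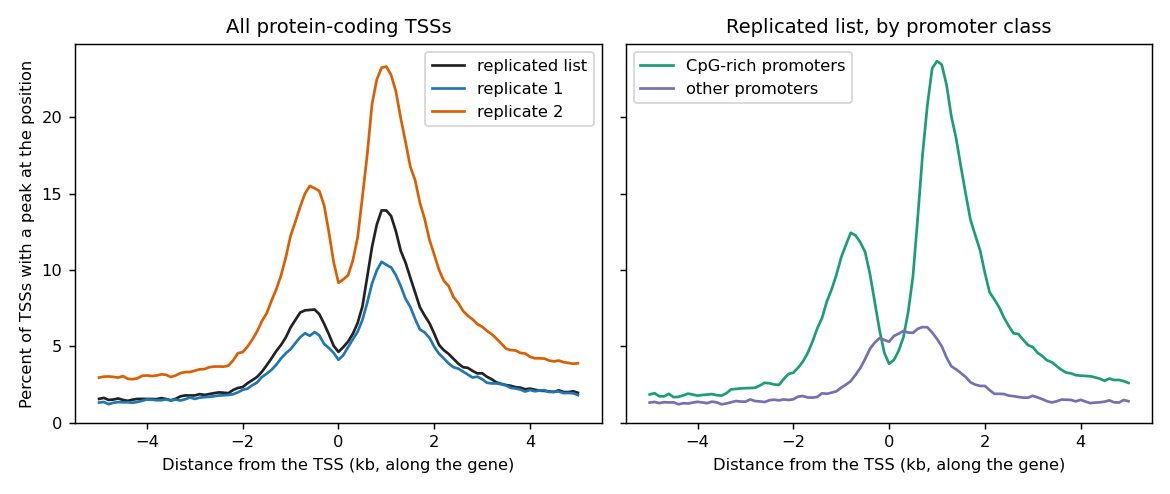
Percent of protein-coding TSSs with a peak at each position along the gene, in kb from the TSS. The left panel shows all TSSs for the replicated list and both replicates, and each line dips at the TSS with a higher maximum downstream. The right panel shows the replicated list for CpG-rich and other promoters, which reach 23.7% and 6.26% downstream.

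Relative to other orderings of the same bases, 7 of 14 motifs had a higher density in distal peaks than in their flanks on all autosomes. Homeodomain sites (TAATTA) were 1.93 ± 0.12 times as dense in 45941 distal peaks as in 79422 flanks, each relative to other orderings of the same bases (SD, n = 19 autosomes). The octamer of POU factors (ATGCAAAT) had a ratio of 1.68 ± 0.25 and the E-box CAGCTG 1.39 ± 0.06. The E-boxes CAGCTG and CAGATG were both chosen as sites of neural helix-loop-helix factors, and only CAGCTG was higher on all autosomes. The SOX sites ACAAAG and ACAATG had 1.23 ± 0.06 and 1.22 ± 0.07, the NFI motif TTGGCA 1.16 ± 0.05 and the TEAD site CATTCC 1.10 ± 0.05. The E-box CAGATG (1.01 ± 0.04), AP-1 (1.04 ± 0.11), GATA (1.07 ± 0.08), ETS (1.10 ± 0.15), RFX (1.01 ± 0.08), SP (1.05 ± 0.06) and HNF4 (1.11 ± 0.40) sites did not have ratios above 1 on all 19. The ratio for TAATTA rests on the division by other orderings: its plain density was 0.286 per kb in peaks and 0.300 in flanks. Against flanks matched on GC, without that division, it was 1.92 ± 0.22, while AP-1 was at 0.898 ± 0.13, CAGATG at 0.958 ± 0.05 and the SP site at 1.42 ± 0.17. ETS (1.26 ± 0.21), RFX (1.17 ± 0.10) and GATA (1.13 ± 0.10) sites then had higher ratios than the TEAD (1.08 ± 0.06) and NFI (1.11 ± 0.06) sites, and SP, ETS, RFX, GATA and TEAD sites were each above 1 on 18 of 19 autosomes. In the main comparison repeated on the stronger peaks by fold, the POU octamer was above 1 on 18 of 19, as was the TEAD site in the list of replicate 1 alone.

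Peaks were richer in GC than their surroundings. The median GC content was 53.7% in promoter peaks, 50.5% in distal peaks and 45.7% in the flanks of distal peaks, a difference of 4.79 points between the last pair. The observed over expected CpG was 0.392, 0.236 and 0.183. In the replicates the difference between distal peaks and flanks was 4.61 points (replicate 1) and 3.72 points (replicate 2).

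Chromosome X carried few peaks. The replicated list had 223 peaks on X, 1.36 per Mb, against a mean of 28.5 ± 7.01 per Mb over the autosomes (SD, n = 19), a ratio of 0.0479. The lowest autosome, chromosome 16, had 19.3 per Mb and the highest, chromosome 11, 46.2. The ratio was 0.0628 in replicate 1 and 0.122 in replicate 2, and 0.0207 among replicated peaks with a −log10 q of at least 2. All 4 lists had no peak on chromosome Y. Genes on X, such as Arx, Plp1 and Hprt, were ranked among genes of all chromosomes, so their ranks include this lower level.

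**Figure D4:**
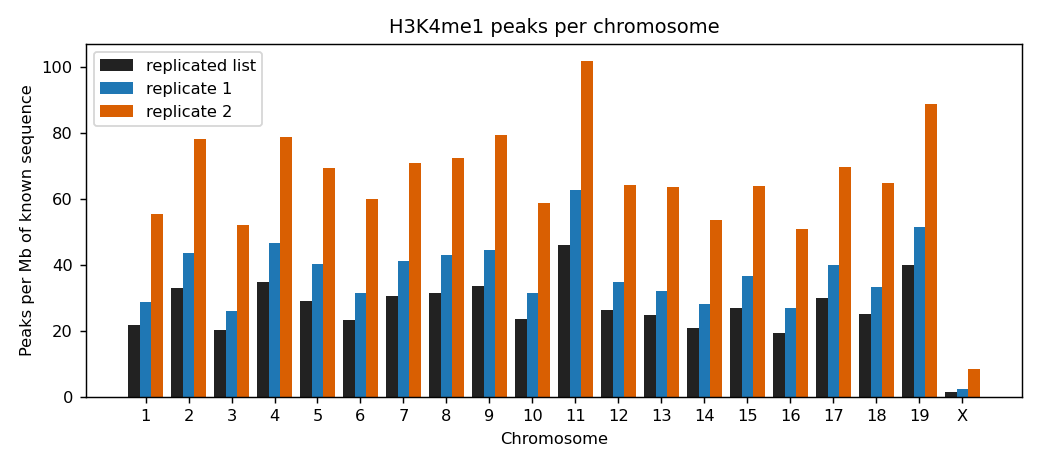
Peaks per Mb of known sequence on each chromosome in the replicated list and in replicates 1 and 2. Autosomes range from 19.3 to 46.2 per Mb in the replicated list, and chromosome X has 1.36.

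The replicates were then compared. They shared most of the loci with the strongest marking and differed in the extent of the lists. Of replicate 1 peaks, 68.6% overlapped a replicate 2 peak, against 3.86% by chance (highest shift 5.04%), and of replicate 2 peaks 34.1% overlapped a replicate 1 peak, against 2.11%. With both lists at the same number of peaks the shares were 55.4% and 46.4%. Requiring 50% of both peaks, a stricter rule that can only lower the shares, gave 26.1% and 14.5%. The Jaccard index of covered bases was 23.4%. Among peaks in the highest fold group of 4 equal groups, 87.0% of replicate 1 and 62.0% of replicate 2 were shared, against 59.5% and 18.7% in the lowest. Over 51947 pairs of overlapping peaks the log2 fold correlated with a Spearman rho of 0.274 and a Pearson r of 0.299, across peaks, which are not independent replicates.

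Over genes the replicates were closer. The covered percent of the window, with both lists at the same number of peaks, correlated with a rho of 0.938 and an r of 0.963 across genes, which are not independent replicates either. At that number replicate 2 covered more, 2.68% of the mean window against 1.73%. The largest excess in replicate 2 was at Gse1 (55.3% against 41.8%), Gnat1 (25.6% against 15.3%), Vamp2 (18.3% against 8.41%), Auts2 (20.3% against 10.5%) and Sox1 (19.2% against 9.48%). The largest in replicate 1 was smaller, at Gng7 (4.32% against 2.20%), Man2a2 (6.43% against 4.32%), Lemd2 (4.73% against 2.76%), Tmod1 (2.39% against 0.723%) and Cyp26c1, which encodes an enzyme that breaks down retinoic acid (3.31% against 1.74%). With 1 library per replicate these differences have no test.

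All 67641 replicated peaks had the coordinates of a pooled peak, so the replicated list was 79.5% of the pooled one. The 17437 pooled peaks left out were narrower, at a median of 179 bp against 289 bp, with a median fold of 2.96 against 3.55, and 70.9% of them lay over 5 kb from a TSS against 67.9%. Most of those left out lacked a peak in replicate 1 (81.0%), and 12.4% lacked one in replicate 2. Among the replicated peaks 15587 overlapped no replicate 1 peak and 1217 no replicate 2 peak, so the list is not limited to peaks found in both replicate lists. All pooled peaks that shared 50% of either peak with a peak of each replicate, 49654, were in the replicated list.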

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

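All tests in this part were chosen after the data were seen, and so were the bounds that decide them, except that the bound for the midbrain and hindbrain list matched on window GC was set before that value was computed. The 0.1 bound on the spread of the implied X dose, the requirement of at least 20 X peaks behind a setting and the matching per replicate were set after a first look at the same values.

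Outside the chromosomes used for the comparisons, replicate 1 had 4 peaks on unplaced or other sequences, with folds of 3.78, 3.49, 1.62 and 1.42. The other lists had 0. The count was flagged because it passed a floor of 3, which does not test whether the lists differ.

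Chromosome X had few peaks, at 0.0479 of the autosomal density. In 1 Mb windows matched on the number of protein-coding TSSs and on GC, X still had 0.130 of the peaks expected (0.173 in replicate 1 and 0.278 in replicate 2), while the lowest autosome had 0.840, which argues against gene density and GC content as the whole cause. Pools of both sexes carry fewer copies of X than of an autosome, from 0.5 for males to 1 for females, and a candidate explanation is that this lower dose loses most peaks against a genome-wide background: the dose that gives the observed X peaks was 0.598 to 0.675 over 13 combinations of replicate and pileup minimum, a spread of 0.0768. In replicate 2, 568 X peaks reached a pileup of 10, where 2462 would be expected at full dose, 986 at a dose of 0.75 and 181 at 0.5. These pileups were computed from the fold of every peak with 1 constant background per replicate. Only 45.9% of replicate 1 peaks and 44.1% of replicate 2 peaks met that decoding within the stated limits, so the implied doses are approximate. A pool with equal numbers of both sexes would have a dose of 0.75, and all 13 implied doses lay below it, with a median of 0.637. If these approximate doses hold, copy number alone would need more males than females in both pools. The 13 doses come from nested pileup minimums of the replicate lists and are not separate tests. Expected peak numbers were matched on TSS number and GC only, so other differences between X and the autosomes were not excluded. The sex ratio of the pools is not given in the sources used here, so less H3K4me1 on an inactive X cannot be told apart from a lower dose.

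Replicate 2 had the longer list, and the pooled list was shorter than either replicate's. Deeper sequencing of replicate 2 as the whole cause is argued against by the number of peaks at a fold of 5 or more, which was 3.79 times that of replicate 1 (15013 against 3964) while the backgrounds differed by 1.10 times. The ratio rose at each step of the fold threshold, from 1.63 at 3 to 22.1 at 8 (375 against 17 peaks), consistent with stronger enrichment in replicate 2; the pools differ in embryos as well as in libraries, and no biological explanation was tested. In the 43.4% of pooled peaks whose columns could be decoded within the stated limits, 1 fragment counted as 0.541 in the fold. This value was estimated from the folds of the pooled list and the background implied by its p-values, without the replicate lists. The pooled background over the summed backgrounds of the replicates gives the same value to 3 digits. The pooled background enters both values, so they are not fully separate. Such a match would follow if pooled fragments had been scaled down.

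Genes of midbrain and hindbrain and of the Hox clusters were covered in forebrain along with the forebrain lists. Against random lists matched on window GC the midbrain and hindbrain list stayed at the 99.8th percentile, which argues against GC content as its whole cause, while the Hox list fell from 99.77 to 9.07, so that the GC content of its windows may account for its coverage; its median was unchanged at 2.57%, and the median of the random lists moved from 0.774% to 3.30%. Tissue of the neighbouring midbrain in the dissection cannot be told apart from marking of these genes in forebrain cells, since peak lists carry no cell of origin: 33.3% of the midbrain and hindbrain members lay above the 90th percentile of their length decile (Pax2, Pax3, Pax5, Pax7 and Lmx1b). Of the biology the labels name, tissue and stage, neither varied, so no biological explanation was tested.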

How the results depend on the processing

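The 5′ ends of all transcripts and the added matching of random lists on window GC and promoter CpG class were chosen after seeing the data; all other settings were fixed before the data were examined. Of 66 settings for the comparisons, 34 moved the value and 32 did not, and reversals were not scored for them. Of the 32, 12 left a value within its tolerance and 20 left a count within 1.5 times its size. The tolerance was the SD between replicates for the distal share, the genic share, the TSS ratio, the X ratio and the GC difference. For the overlaps and the replicated share of pooled peaks it came from a 95% Wilson binomial interval, and for rho from a 95% interval over peak pairs. Those intervals do not measure a spread between replicates. The cause was not tested except where the setting itself gives it. For single gene lists, 271 of 286 settings kept the side of the threshold, 7 ended a call and 8 made one (242 fixed settings: 234, 2 and 6). Of the 7, 2 are those of the olfactory receptor list under the added matching, where many random lists also had a median of 0. Among genes of like window GC or promoter CpG class that list did not stand apart. For single motifs, 24 of 70 left the ratio within the SD between the ratios of the replicates, and the 46 others moved it. That SD is not the SD over autosomes printed with each ratio, so a moved ratio can lie within its printed SD.

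Overlap of the replicates (68.6% of replicate 1 and 34.1% of replicate 2) was 59.0% and 19.5% when 50% of the peak's own length was required, 26.1% and 14.5% with 50% of both peaks, 55.4% and 46.4% with the same number of peaks, 71.8% and 25.6% with a −log10 q of at least 2, and 62.7% and 31.1% among the stronger peaks by fold. The rho of 0.274 was 0.332 with 50% of both peaks, 0.285 for −log10 p, 0.262 with the same number of peaks and 0.237 at −log10 q of at least 2. The replicated share of pooled peaks, 79.5%, was 97.2% at −log10 q of at least 2. The share over 5 kb from a TSS, 67.9%, was 66.7% at −log10 q of at least 2, 66.2% among the stronger peaks, 58.4% with TSSs of all gene types and 62.2% with the 5′ ends of all transcripts, since both add TSSs. The genic share, 72.6%, was 74.3% at −log10 q of at least 2. The share of TSSs in a peak over the downstream maximum, 0.334, was 0.336 in the pooled list, 0.287 at −log10 q of at least 2 and 0.320 among the stronger peaks. Of the 10 broadest clusters, 5 remained when joined at 1 kb, 5 at the longer distance and 5 at −log10 q of at least 2.

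With 1 replicate's list in place of the replicated list, the share over 5 kb from a TSS was 72.0% to 73.4%, the genic share 69.9% to 72.0%, the TSS ratio 0.391 to 0.393, the X ratio 0.0628 to 0.122 (main 0.0479), the clusters kept 6 to 8 of 10, and the GC difference 3.72 to 4.61 points (main 4.79). Lists above the threshold numbered 8 to 11 over all settings (main 9), and motifs above 1 on all autosomes 6 to 7 (main 7): the POU octamer was lost among the stronger peaks, and TEAD in replicate 1 alone and against flanks matched on GC, where the ratio is not divided by other orderings. Read totals are not given in the sources used here, and no test varied depth. With a median pileup of 9 to 10 fragments among the peaks that could be decoded, depth limits how precisely the fold of a single peak is known.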

Other observations

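The gene groups and microRNA genes in this part, and the tests of transcription factor genes, were chosen after the values were seen, except that the test within CpG-rich promoters was fixed before its result. Its companion within other promoters, and the reading of both together, were settled after that result, because only 6 other genes had a CpG-rich promoter.

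Further gene groups are given as values only, since 16 groups were put together after genes such as Gse1, Notch1, Cbx8 and Efna2 had been seen to be widely covered, and a group built around such genes does not test itself. The median share of the window is followed in brackets by the median of random lists of like gene length and of random lists also matched on window GC. Members with overlapping windows were each counted, so the highest values within a group can come from the same peaks. Eph receptors and ephrins, which guide axons and set tissue borders, had 6.27% (0.806%; 1.59%), with Efna2 (21.7%), Ephb2 (18.8%) and Efnb3 (12.2%) highest. Genes of the Notch pathway had 5.28% (0.810%; 2.28%), with Notch1 (23.7%), Lfng (13.0%) and Notch2 (12.8%) highest, and semaphorins and plexins, also guidance genes, 4.96% (0.821%; 1.84%), with Sema3b (21.4%) and Sema3f (17.1%). Transcriptional corepressors had 4.73% (0.753%; 1.83%), with Gse1, Ncor2 and Tle3, Sox factor genes 4.61% (0.690%; 1.09%), and Polycomb group genes 3.66% (0.840%; 1.44%), with Cbx8 (22.9%), Cbx4 (20.8%) and Cbx2 (15.5%). Zic genes had 5.09% (0.946%; 0.366%), LIM homeobox genes 3.58% (1.03%; 1.75%), retinoid pathway genes 2.38% (0.825%; 1.69%) and Fox factor genes 2.04% (0.743%; 1.496%).

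Ionotropic glutamate receptor genes had 0.775% (0.669% and 1.05%), and 6 of 18 lay above the 90th percentile of their length decile. Grik3 was highest at 10.4%. Keratin genes had 0.547% (0.891%; 2.37%). Medians of 0 were those of cytochrome P450 genes (69 of 107 without a peak; 0.903%; 0.359%), vomeronasal receptor genes (315 of 330; 0.862%; 0), beta-defensin genes (31 of 42; 0.738%; 0.164%) and protocadherin genes (53 of 68; 0.706%; 0.231%). Among the last, Pcdhgc3, Pcdhgc4 and Pcdhgc5, at the end of the gamma cluster, had 18.01%.

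MicroRNA genes of the nervous system differed by copy. The 100 kb windows of Mir9-3 (chromosome 7, 79505264 to 79505353) and Mir9-1 (chromosome 3, 88215598 to 88215686), copies of a microRNA of neural progenitors, were covered to 31.1% and 25.5% (replicate 1 23.8% and 20.0%, replicate 2 38.9% and 31.8%), more than in 99.9% of protein-coding genes. The third copy, Mir9-2 (chromosome 13, 83738814 to 83738885), had 1.43%. The copies of the neuronal microRNA miR-124 had 6.48% (Mir124a-3), 3.44% (Mir124a-1) and 2.28% (Mir124a-2).

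A hypothesis was that transcription factor genes may be marked irrespective of tissue. In the 9 lists of other tissues and cell types their difference from the lists' other members did not pass the threshold after adjustment. The median percentile within the length decile was 73.0 for 47 factor genes and 56.9 for 76 others, a difference of 16.1 points (permutation test, two-sided, 100000 resamples, p = 0.0254; adjusted p = 0.102 over 4 tests), and it was in this direction in 5 of 9 lists (opposite in head mesenchyme, endothelium, skeletal muscle and endoderm). The permutation treats genes as independent, although some, such as C1qa, C1qb and C1qc, share windows. Among factor genes, Prrx2 (6.47%), Grhl3 (6.75%), Nfe2 (7.37%) and Klf1 (7.64%) had the highest ranks. A CpG-rich promoter was present in 48.9% of factor genes and 7.89% of others. Among genes with a CpG-rich promoter the difference was 2.68 points (23 against 6 genes, exact permutation test, p = 0.494, adjusted p = 0.659) and among the rest 2.63 points (24 against 70, permutation p = 0.804, adjusted p = 0.804). The overall difference, if it holds, is consistent with promoter CpG content, and marking of factor genes as such cannot be told apart from it, because few genes combine a CpG-rich promoter with another function; without the head mesenchyme list it was 14.3 points (permutation p = 0.102, adjusted p = 0.205).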
